A study of Macaca mulatta with 3 samples.

How the data were processed

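The series measured chromatin accessibility by ATAC-seq, in which a transposase inserts sequencing adapters into open chromatin, in peripheral blood mononuclear cells (PBMCs) of 3 female rhesus macaques. PBMCs are the lymphocytes, monocytes and other round-nucleated white cells that a density gradient separates from blood. Per the labels' protocols, the cells came from 4 mL of blood, were held in medium at 500000 cells per mL and 35 °C for 90 minutes, and 50000 cells entered each library without the lysis step, an omission meant to lower the mitochondrial share of the reads. The libraries were sequenced as read pairs of 38 bp. The samples belong to study phase 2 and to 1 group, and no label gives the social rank of an animal, so the series holds no comparison between groups or animals.

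The authors deposited 1 list of peak summits for the whole series. BWA and MACS2 are named in the submitters' processing notes, without versions. The genome build, the filters on reads (duplicates, mapping quality, mitochondrial reads) and any shift of the reads to the transposase cut site are not given in the sources used here, nor is how the 3 libraries were combined. Each row of the list holds a chromosome, a position of 1 base, a peak name and a score. From the values, the score was read as −log10 of the q-value that the authors' peak caller gave to the summit: the lowest score, 1.302, lies just above −log10 of 0.05, which is 1.301. The scores are the peak caller's own values and belong to the combined data. They therefore carry no SD or n, and the replicate error of a summit is unknown. The read depth per animal is unknown as well, since the list holds no counts. None of the 48877 names carries the letter suffix that marks several summits in 1 peak, so a summit stands for a peak throughout, and the planned comparison of peaks with several summits was void.

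Positions are given 1-based in the coordinates of the list, with its chromosome names without the prefix and the leading zero. The list splits a chromosome into 2a and 2b and has no chromosome 20, so its numbering differs from that of the gene table below, and which chromosome of another assembly a number stands for was not established. A gene table of the assembly T2T-MMU8v2.0 was tested as a possible match. It shared 19 of the 21 chromosome names of the list and lacked 2a and 2b. On the shared names, 2.74% of 45078 summits lay within 1 kb of an end of a protein-coding gene, and 2.66% did on average after the summits were moved by 10 distances of up to 1000 kb (range 2.54% to 2.76%). The ratio of 1.03 was below the limit of 3 fixed for a match, and 1162 summits on 4 chromosomes lay beyond the last gene of the same-named chromosome. A different build and a different numbering of the chromosomes would both give such values, and the test does not separate them. The coordinates of the list and of this table were therefore not joined. The planned results on promoters, annotation classes, 18 gene lists (blood cell types, immune responses and unrelated tissues), 26 sequence motifs and GC content were not run, and no summit is assigned to a gene here. For the same reason the planned rule for naming items covered regions only: the 10 summits with the highest score and the 10 clusters with the most summits.

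Summits per chromosome were divided by the span from the first to the last summit, and compared with the number expected if every chromosome had the same number per Mb. Intervals are 95% bootstrap intervals from 1000 draws of blocks of 1 Mb within chromosomes, because neighbouring summits are not independent; exact Poisson intervals are narrower. Clusters joined summits at most 10 kb apart, and were set against 100 random placements of the same number of summits per chromosome. The surroundings of a summit were counted as other summits with a score under 1000 at 10 to 50 kb, leaving out the nearest 10 kb, over which MACS2 by default can take its local background. For these counts, summits of 1 score class within 100 kb of each other were taken as 1 locus. Group differences were tested by two-sided permutation tests with 100000 resamples or by Fisher's exact test. The shares of summits carry exact Clopper-Pearson 95% intervals. These and the Poisson intervals cover counting error only.

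The choices fixed before the data were examined were the density and clustering measures, the build test, and the alternatives of a minimum score of 5 or 10, other cluster distances, another span and placement within bins of 1 Mb. The score classes, the block bootstrap, the counts of surrounding summits, the comparison of clustered and isolated summits and the windows at chromosome starts were chosen after seeing the data. The code was tested on 48877 simulated summits. A density ratio set to 0.504 on X and 2.02 on 19 was recovered as 0.506 and 1.99. On simulated Poisson counts, in smaller groups than those compared below, the permutation test called 7% of equal groups and 88% of groups whose means differed by a factor of 2. These rates do not give the error rate or power of the tests below, whose groups differ in size and spread. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 were used.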

Results

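To map regions of open chromatin in macaque blood cells, ATAC-seq was carried out on PBMCs of 3 female rhesus macaques. The animals formed 1 group, and their libraries gave a single list of 48877 peak summits on 20 autosomes and X. These are called sites below. The filters on reads are unknown, so not every site is shown to be accessible chromatin. The list held no value per animal, so the differences below compare regions within the combined list, and the spread between animals could not be assessed. The genome build was not given in the sources used here, and regions are named by the coordinates of the list without gene names. Chromosome numbers are also those of the list, and a number may not stand for the chromosome that has it in other rhesus assemblies.

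Most sites were weak by the peak caller's measure, and a small number were extremely strong. The median score (−log10 of the q-value) was 5.20, the quartiles were 2.92 and 14.3, and the 99th percentile was 128. A score of at least 10 was reached by 15945 summits, which is 32.6% of the list (exact 95% interval 32.2 to 33.0). Above a score of about 150 the distribution had a long tail. The number of summits fell by a factor of 9.74 from a score of 50 to a score of 150, from 3741 to 384. Over the wider step from 1000 to 10000 it fell only from 168 to 28. The 168 summits with a score of at least 1000 made up 0.344% of the list (exact 95% interval 0.294 to 0.400).

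**Figure D1:**
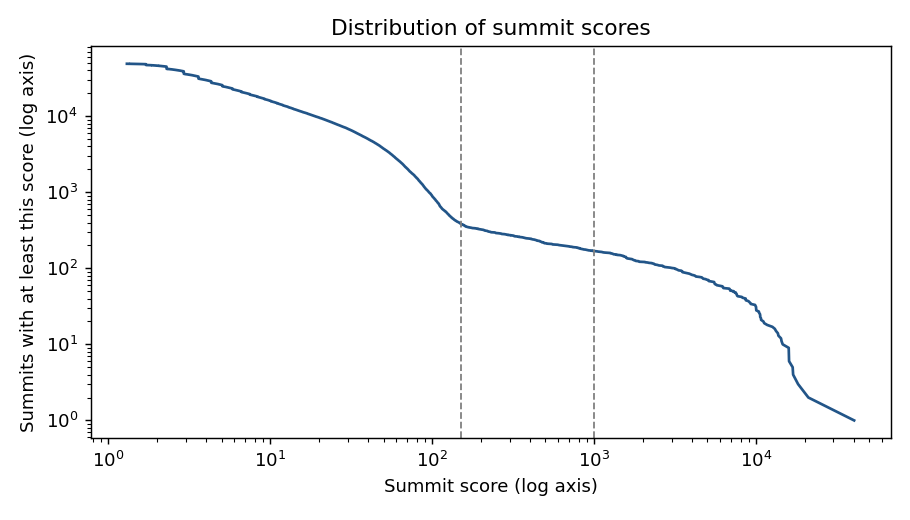
Number of summits (log axis) with at least the score on the horizontal axis (log axis, −log10 of the q-value); dashed lines mark scores of 150 and 1000. The curve falls steeply up to about 150 and then flattens, with 168 summits at 1000 or more and a highest score of 40244.

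Sites were spread unevenly over the chromosomes. Chromosome 19 had the highest density, with 39.4 summits per Mb, which was 2.27 times the number expected at the density of the whole list, 17.4 per Mb (95% block bootstrap interval 2.00 to 2.52). It was followed by chromosome 17 with 29.2 per Mb (1.68 times, 1.48 to 1.88), chromosome 15 with 24.6 per Mb (1.42 times, 1.26 to 1.58) and chromosome 1 with 23.9 per Mb (1.38 times, 1.27 to 1.49). The lowest densities were those of chromosome 4 with 10.95 per Mb (0.631 times, 0.555 to 0.715), X with 11.1 per Mb (0.639 times, 0.557 to 0.731) and chromosome 18 with 11.8 per Mb (0.681 times, 0.554 to 0.815). Chromosome 19 thus had 3.55 times the density of X. The interval lay above 1 for 5 chromosomes, below 1 for 8 and held 1 for the other 8. With blocks of 5 Mb it lay above 1 for 4 and below 1 for 5.

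**Figure D2:**
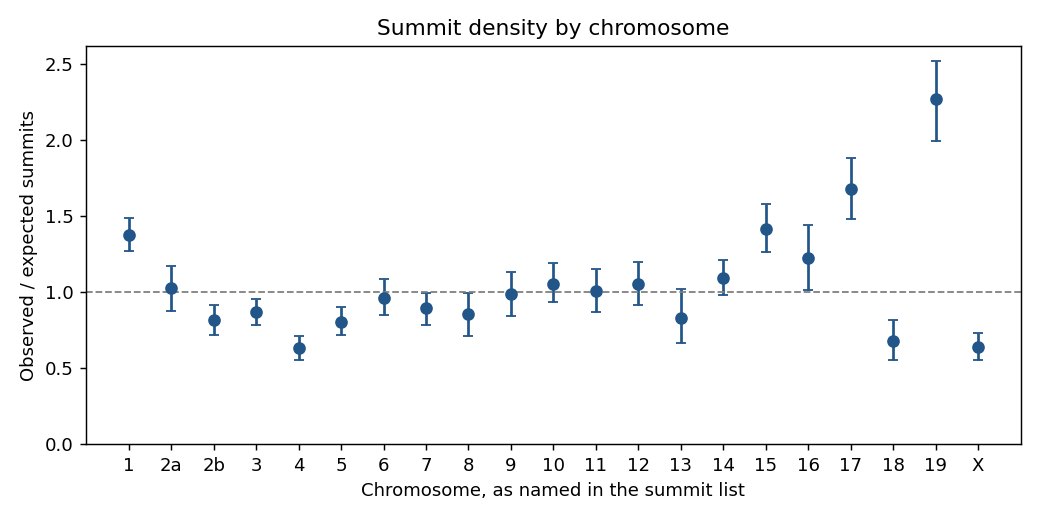
Observed over expected number of summits for each chromosome; points are the ratios, bars the 95% block bootstrap intervals over 1 Mb blocks, and the dashed line marks a ratio of 1. Chromosome 19 lies at 2.27 and chromosomes 4, X and 18 between 0.631 and 0.681.

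Chromosomes with more sites tended to have a larger share of strong ones, with exceptions. On chromosome 19 the median score was 11.02 and 53.3% of the 2093 summits had a score of at least 10 (exact 95% interval 51.2 to 55.5). Chromosomes 16 and 17 followed with 40.9% (38.4 to 43.3) and 40.3% (38.2 to 42.3). The share was lowest on chromosome 18, at 24.8% (21.9 to 27.9), and on 2b, at 26.7% (24.7 to 28.8). Chromosome 1, the 4th in density, had 31.3% (30.04 to 32.53), below the 32.6% of the whole list. X had 29.5% (27.3 to 31.8), below the 32.7% (32.3 to 33.2) of all 47225 autosomal summits. Across the 21 chromosomes, density and the share of such summits were correlated, with Pearson's r = 0.88 (permutation p = 1e-05, the smallest that the resamples can give) and Spearman's rho = 0.75 (permutation p = 0.00016). Without the 2 chromosomes farthest from the median density, 17 and 19, r was 0.61 (permutation p = 0.006) and rho was 0.67 (permutation p = 0.0024). This was the only relation across chromosomes that was computed. The over-representation of chromosome 19 rose to 3.71 times when only summits with a score of at least 10 were counted, while that of chromosome 1 was 1.32 times.

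Sites also lay closer together than chance would place them. Of all summits, 47.1% had another summit within 10 kb. In 100 random placements of the same summits along each chromosome, 30.9% ± 0.28 (SD over placements) did, and at most 31.6%. When summits were placed at random within their own 1 Mb bin, 39.95% did and at most 40.37%, so part of the excess lay at distances below 1 Mb. Joining summits at most 10 kb apart gave 8633 clusters and left 25879 summits isolated. There were 485 clusters of 5 or more summits, against 51.7 ± 7.17 (SD) in the random placements along whole chromosomes. Cluster sizes were not compared with placement within 1 Mb bins, so this excess includes differences in density between bins. Per bin of 1 Mb the median was 14 summits, 66 of 2829 bins had none, and the densest 10% of the bins held 27.6% of the summits.

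Sites were more frequent near the starts of the chromosome sequences than in the list as a whole; the other ends were not assessed, because the lengths of the sequences are unknown. In 19 of 21 chromosomes a summit lay within the first 10 kb. The first summit of these chromosomes lay between position 143, on chromosome 17, and position 9380, on chromosome 9. Chromosomes 10 and 15 had their first summit at 18176 and 29671. The density was 181 summits per Mb in the first 10 kb (38 summits, exact Poisson 95% interval 128 to 248) and 54.0 at 10 to 100 kb (44.0 to 65.5). It was 42.6 at 100 to 1000 kb (39.7 to 45.6) and 24.4 at 1000 to 5000 kb (23.3 to 25.4), against 17.4 over the whole list. Chromosome 8 alone held the cluster of 70 summits described next. Without this chromosome the first 2 values were 165 (114 to 232) and 36.1 (27.9 to 46.0). The median score of the 38 summits in the first 10 kb was 14.7, against 5.19 for all others (two-sided permutation p = 0.0004). This test took the 38 summits as independent, although they came from 19 chromosomes, so its p can be too small.

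**Figure D3:**
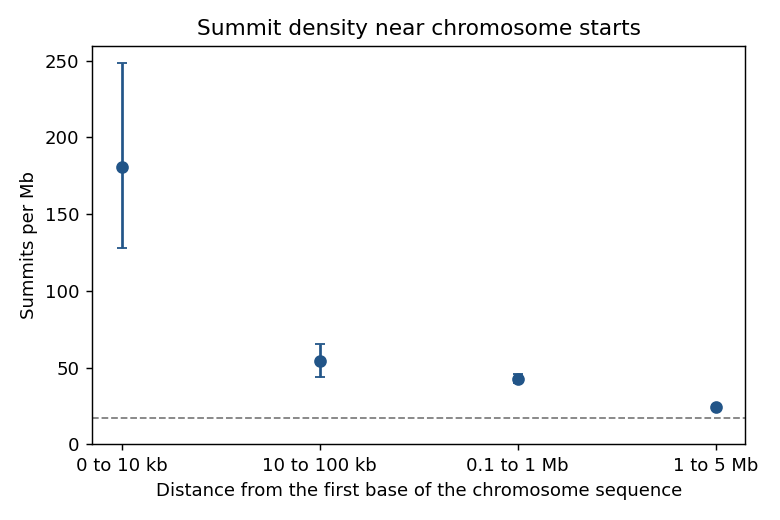
Summits per Mb over the 21 chromosomes by distance from the first base of the sequence; points are densities, bars exact Poisson 95% intervals, and the dashed line is the density of the whole list, 17.4. The density falls from 181 in the first 10 kb to 24.4 at 1 to 5 Mb.

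The 10 largest clusters lay on 6 chromosomes. The largest cluster held 97 summits on chromosome 13, from 8929111 to 9147886, with a median score of 7.57. The largest cluster in any random placement along whole chromosomes held 13 summits. Placement within 1 Mb bins was not used for this comparison. Cluster size depended on the settings: the largest cluster held 34 summits when only those with a score of at least 10 were used, 34 with summits joined at 5 kb and 148 with summits joined at 50 kb. A second cluster of 45 summits began nearby on chromosome 13, at 9163428, and ended at 9256735, and a cluster of 61 lay on the same chromosome from 2289817 to 2403952. On chromosome 8, 70 summits lay from 188 to 169643, at the very start of the sequence, and 68 from 7459114 to 7637723. Chromosome 10 held 68 summits from 405649 to 576532, X held 44 from 88883721 to 88998574, and chromosome 9 held 42 from 105920727 to 106026250. In these 8 clusters the median scores were between 4.76 and 9.09, and 1 summit, in the second cluster on chromosome 8, reached a score of 1000 (1266). The other 2 of the 10 largest clusters had higher median scores. The cluster of 36 summits on chromosome 4, from 83191924 to 83255539, had a median score of 131, and 4 of its summits reached a score of 1000. The cluster of 33 on chromosome 9, from 94543000 to 94610173, had a median score of 306, and 6 of its summits reached 1000.

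Clustered summits had somewhat higher scores than isolated ones in the whole list. With 1 summit drawn per cluster, the median score was 5.84 over 8633 clustered summits and 4.45 over 25879 isolated summits (two-sided permutation p = 1e-05, the smallest that the resamples can give). The permutations were not made within chromosomes, so differences between chromosomes in density and score can add to this difference. The share of summits with a score of at least 10 was also higher in clusters, from 30.8% of isolated summits to 42.3% of those in clusters of 10 or more. Among the summits above such a minimum, which is set on the score itself, the clustered median was the lower one. With a minimum of 10 the difference was −3.05 when clusters were formed again from the remaining summits and −7.23 when the clusters of the whole list were kept (21.7 over 5076 clustered and 28.95 over 7961 isolated summits; two-sided permutation p = 0.0001 for both, the smallest that 10000 resamples can give).

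The highest score in the list, 40244, was that of a summit on chromosome 11 at 18663875. The next were on chromosome 4 at 31709244 (score 20998), chromosome 3 at 190907434 (18140), chromosome 4 at 71129961 (16904) and chromosome 17 at 63083798 (16795). They were followed by chromosome 6 at 98402489 (15957), chromosome 14 at 111011029 (15917), chromosome 10 at 18406753 (15908), chromosome 5 at 23380917 (15877) and X at 118542254 (14578). Of these 10 summits, 5 had no other summit with a score under 1000 at 10 to 50 kb, whereas the summit on chromosome 3 had 37.

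The surroundings of the strongest summits differed from those of ordinary strong summits. The 168 summits with a score of at least 1000 formed 133 loci. Of these, 44 (33.1%) had no other summit with a score under 1000 at 10 to 50 kb, compared with 433 of 2367 loci (18.3%) with a score from 50 to under 150 (Fisher's exact test, two-sided, p = 9.14e-05). The counts left out other summits of the extreme class but not those of the strong class, which can raise the share without a neighbour at extreme loci. The medians were 1 and 2 other summits. The means went the other way, with 2.89 ± 5.37 (SD) against 2.504 ± 2.73 (SD), with no difference past 0.05 (two-sided permutation p = 0.131). This result changed with the setting: the difference, 0.39, was 0.54 when only summits with a score of at least 10 were counted (permutation p = 0.00255) and −0.045 at 10 to 100 kb (permutation p = 0.919). The permutation test takes the spread of both groups as equal, which it was not, so its p-values can be too small. In 8 of the 133 loci there were 10 or more other summits. Random places on the same chromosomes had a mean of 1.42 (95% range of 1000 draws 1.13 to 1.71), and 41.5% of them had no other summit (95% range 33.1 to 50.4).

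**Figure D4:**
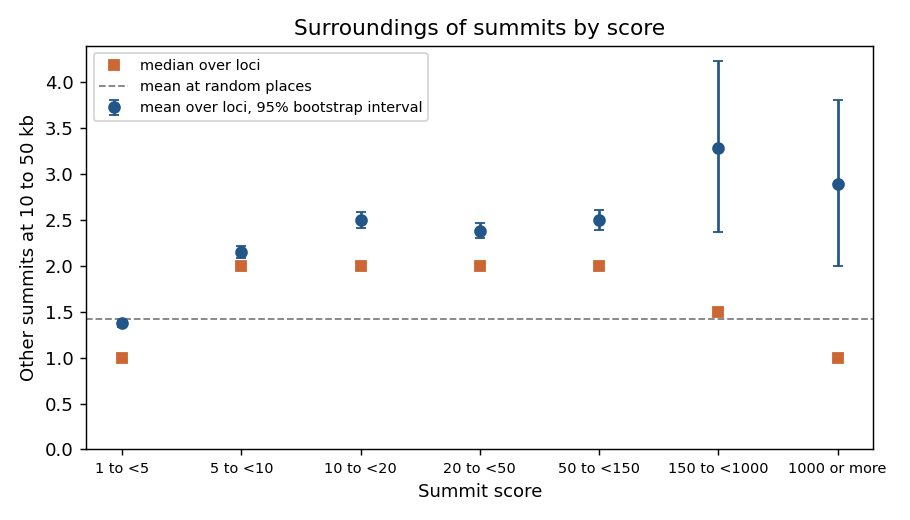
Number of other summits with a score under 1000 at 10 to 50 kb by score class of the summit. Circles are means over loci with 95% bootstrap intervals, squares are medians, and the dashed line is the mean of 1.42 at random places. The median is 1 below a score of 5, 2 from 5 to under 150 and 1.5 from 150 to under 1000. It is 1 at 1000 or more, where the mean is 2.89. Merging within 100 kb left 8291 loci of 23143 summits below a score of 5, and 133 of 168 at 1000 or more. The classes were thus thinned unequally, so the trend over scores can partly reflect the merging.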

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

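Taking 1 summit per peak removes no summit and tests nothing, so its 14 values are not counted here. Of the 70 other values recomputed under alternatives, 52 kept their direction and their side of the test's threshold or, where there was no test, stayed within the interval or within 1.5 times of a count; 10 moved, 3 gained significance and 5 changed sign. The 52 include every value without summits of a score of at least 1000. That setting kept 48709 of 48877 summits and so could hardly change a value. Among the 52, 5 tested values moved by over 1.5 times and are given below. The causes were not tested, except where fewer summits enter by construction. A minimum score of 5 or 10 left 25734 or 15945 summits. With these minimums the ratio of observed to expected summits moved to 3.20 and 3.71 on chromosome 19 and to 1.97 and 2.08 on chromosome 17, and with a minimum of 10 to 0.519 on chromosome 18. The difference of median scores between clustered and isolated summits turned to −1.11 and −3.05, or −3.13 and −7.23 with the clusters of the whole list kept, and was 0.84 with clusters joined at 5 kb. The mean number of other summits at extreme minus strong loci was not significant in the main setting (0.39). It was larger and past 0.05 with a minimum score of 5 (0.43, permutation p = 0.0407) or 10 (0.54, permutation p = 0.00255). The same held with the nearest 10 kb included (0.62, permutation p = 0.047). The difference was 0.52 within chromosomes (permutation p = 0.0579). The difference fell to 0.055 for a score of at least 300, with only other summits under 300 counted (permutation p = 0.806). It changed sign at 10 to 100 kb (−0.045, permutation p = 0.919). The spread was wider at extreme loci (SD 3.93 against 1.61 with a minimum score of 10), so these p-values can be too small. With that minimum, the median (0 against 1) and the mean with 10% of loci trimmed at each end (0.598 against 0.744) were lower at extreme loci. The share of extreme loci without another summit stayed above that of strong loci in each of the 5 alternatives run (Fisher's exact p from 9.84e-12 to 0.0157). It was 33.1% in the main setting, 21.8% at 10 to 100 kb, and 50.4% and 57.9% with minimum scores of 5 and 10. These counts left out other extreme summits but not other strong ones. Summits were closer together than in each random placement under every alternative, with ratios of observed to random from 1.05 at 50 kb to 2.15 with a minimum score of 10. Leaving out an animal was not possible, because the list combines all 3, and the alternatives on promoters, gene lists, motifs and GC content were not run without a matching genome. The depth of the libraries is unknown, so a region without a summit is not shown to be closed.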

Other observations

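The test of chance at chromosome starts, the use of medians, trimmed means and shares without a neighbour beside the mean, and the comparison of X with the 3 autosomes nearest in density were chosen after the results were seen. The other tests in this part were fixed before their values were computed. The design has 1 group, so no biological explanation was tested against another condition.

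A few scores recurred very often. The 10 most frequent values were carried by 12608 summits (25.8% of the list), led by 2.29 with 2893 summits and 2.92 with 2868. The longest stretch between neighbouring summits was 3.42 Mb, on chromosome 11 from 24470063 to 27894055, and 140 stretches were longer than 1 Mb.

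Summits in the first 10 kb of a chromosome sequence were more frequent than chance placement gave. In 100 random rotations of the summits along each chromosome, 3.37 chromosomes had a summit in the first 10 kb on average and at most 7, so 0 rotations reached the 19 observed. A summit-rich chromosome end is a candidate explanation for the rise over the first Mb. The rule set for it as the whole cause was a density at 10 to 100 kb of at least 0.5 times that of the first 10 kb. The 54.0 per Mb found there was lower, with an interval below that of the first 10 kb. The limit of 0.5 was a choice, and a density that climbs steeply toward the end would also miss it, so this explanation is not excluded. Reads of repeats that pile up at the end of an assembled sequence may add to the rise. That test stays open: 1 of 38 summits (2.63%, exact 95% interval 0.0666 to 13.8) in the first 10 kb had a score of at least 150, against 0.784% of the others (Fisher's exact test, two-sided, p = 0.259). Such scores are so rare that 38 summits can hardly decide it. The share with a score of at least 10 was 63.2% in the first 10 kb. It was 35.3% at 10 to 100 kb and 38.8% at 100 to 1000 kb, a difference that was not tested.

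The summits with a score of at least 1000 carried 55.9% of the summed score in 0.344% of the list. If all were the strongest open chromatin of active regions, they should have at least as many other summits at 10 to 50 kb as strong summits do; the difference of means, 0.39, was on that side but changed sign at 10 to 100 kb (−0.045), the median was lower (1 against 2) and more loci had none (33.1% against 18.3%), so this stays open. Reads from other copies of a sequence, such as mitochondrial DNA or repeats, piled up at random places would give the surroundings of random places. The mean of 2.89 was higher than the 1.42 found there. With 10% of loci trimmed at each end it was higher as well (1.69 against 1.07, 95% range 0.822 to 1.36). This argues against a uniform placement of the set as a whole along the chromosomes. It does not decide about such reads, because copies of a sequence need not lie uniformly. Neighbours with a score under 1000 were also counted whatever their own source. The share of loci with none lay at the lower edge of the range of random places (33.1% against 33.1 to 50.4). This share lay within the range at 10 to 100 kb (21.8% against 15.8 to 31.6). The same held for a score of at least 300, with only other summits under 300 counted (37.1% against 34.3 to 48.9). The share lay below the range with the nearest 10 kb included (27.1% against 28.6 to 43.6). It also did with a minimum score of 5 (50.4% against 54.9 to 69.9) or 10 (57.9% against 64.7 to 79.7). These values describe all loci together, so such reads at part of the loci, or copies in summit-rich regions, were not tested and stay open. The loci's spread over chromosomes could not be told apart from that of all summits (chi-square statistic with simulated multinomial counts, p = 0.574). Nor could it be told apart from that of the span from first to last summit (the same chi-square simulation, p = 0.938).

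X had as few summits per Mb as chromosomes 4 and 18. A lower read depth on X could lower both the number and the strength of its summits, and the share of X summits with a score of at least 10, 29.5%, was below the autosomal 32.7%. The 3 autosomes nearest in density had 29.7%, 24.8% and 29.9%, so X did not stand apart from autosomes with few summits. Because density and this share were correlated across chromosomes, this likeness does not decide whether the read depth on X was lower. All 3 animals were female, and the inactive X chromosome of female cells stays among the open explanations, untested because no male sample was analysed here.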
